A study of Mus musculus with 3 samples.

How the data were processed

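Polyadenylated RNA-seq libraries from activated regulatory T cells of mouse, labelled male and aged 3 weeks, were used. The labels give shearing and a size range, and name the 3 libraries technical replicates 1, 2 and 3 of 1 biological replicate. All 3 formed 1 group. The kit, strandedness, aligner and quantification program are not given in the sources used here.

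Each library had 3 deposited tables. The larger gene table and the transcript table use mm10 and GENCODE M21, and per the file headers their column layout is that of RSEM. Expected counts as deposited are reads that the authors assigned to each gene or transcript from transcriptome alignments, per the deposited library notes, and they are not normalized. The posterior mean columns hold the authors' second estimate of the same estimated counts and TPM. Each file holds 1 library. TPM as deposited was scaled by the authors for length and to a fixed total over all 81881 entries, which include spike-in and transfer RNA entries. FPKM as deposited was scaled by the authors for length and reads. The third deposited table holds whole-number read counts per gene for 22457 genes of GENCODE M4, with the counter and filters not given in the sources used here. In it, counts of the most abundant genes are compressed. Genes with 20000 or more reads in the larger table had a median of 4.54% to 5.28% of those reads in the smaller one, against 52.7% to 53.7% for genes with 100 to 1000 reads, and all 134 to 170 such genes per library stayed within 2 counts per exonic base. This table was used as an alternative only. Readings of level in it are not divided by gene length.

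All 55536 mouse gene identifiers matched the M21 annotation, which gave symbols, positions and biotypes. Where 2 identifiers share a symbol, the one with more reads was used. The other entries were 97 spike-in entries and 26248 transfer RNA entries. They were left out of library sizes and tests and took 0.166% to 0.229% of all reads. Gene totals were 30362256, 28419259 and 31959927 reads in libraries 1, 2 and 3. At this depth a gene of 0 reads allows up to 3 reads, and such limits and intervals cover counting error only, since reads were not molecule-tagged as far as the labels say.

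Gene lists, gene pairs, tests and alternatives were fixed before the data were examined. Genes named are the up to 5 highest and 3 lowest members of each list by mean TPM, all Treg core genes, both genes of each pair, sex-linked genes, the 10 most abundant genes, the 8 with the largest chi-square, list members that passed that test, the 5 most used Trbv and Trav segments, and the isoform genes. A few genes that the rule names are not reported here, though list and pair counts include them. Genes outside this rule are named as such in the closing section.

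Expected counts were rounded to whole numbers for the chi-square test (2 degrees of freedom) against TMM effective library sizes, in genes with a mean of 10 or more reads, adjusted by Benjamini-Hochberg at 0.05. With 1 library per replicate and no second group, no quasi-likelihood contrast could be fitted. The common dispersion came from edgeR 4.0.16 with an intercept only, in R 4.3.3, and DESeq2 1.42.0 gave alternative size factors. Lists were compared by two-sided permutation tests across genes with 100000 resamples on log2(TPM + 1), adjusted over 3 comparisons. The median of each list was placed among 10000 random lists of the same size drawn from 22028 protein-coding genes. A pair's ratio was called larger than the spread where all libraries had 1 sign and the mean exceeded 2 SD. 3 libraries cannot give a small sign-flip p, so no test was made. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

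After the data were seen, each list's median log2 CPM (plus 0.5) in a library was compared with the mean of the other 2, among 10000 random lists matched in 50 expression bins, for lists with 5 or more members of 10 or more reads. GC content and length of each gene's main transcript were taken from the M21 transcripts, and a quadratic trend in both was removed as an alternative.

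The procedures were tested on simulated data. With Poisson counts for 17190 genes, of which 50 were changed in 1 library at each of 4 fold sizes, the chi-square test recovered 54.0% of those changed 1.2-fold, 74.0% at 1.5-fold, 78.0% at 2-fold and 100.0% at 4-fold, and called 8 of 16990 unchanged genes. With no list changed, 2 of 75 list positions lay outside the middle 95%. With no list different, 4 of 200 list comparisons had a permutation p under 0.05. Dispersion was recovered as a coefficient of 0.201 from 0.2.

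Alternatives covered thresholds, pseudocounts (0.1), posterior mean estimates, FPKM, normalization, low-count filters, the other gene table and each library left out. Signal tracks and reads were not used here.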

Results

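Polyadenylated RNA of activated regulatory T cells (Treg), the Foxp3-expressing CD4 T cells that restrain immune responses, was sequenced from primary mouse cells labelled male and aged 3 weeks. The labels describe 3 libraries, which are technical replicates 1, 2 and 3 of 1 biological replicate, here called library 1, library 2 and library 3. The labels do not say how the cells were activated or at which step the libraries parted. Reads assigned to annotated genes numbered 30362256 in library 1, 28419259 in library 2 and 31959927 in library 3. There was 1 group, so no comparison between groups was possible, and every SD below is the spread between these 3 libraries (n = 3), not between animals. Levels are in TPM, transcript abundance scaled for length and total, as deposited. Positions are on mouse build mm10 with GENCODE M21 annotation. Genes detected at 1 TPM or more in all 3 libraries numbered 12995, of which 10601 were protein-coding.

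The genes that define Treg were all expressed. Each of the 24 members of the Treg core list was detected, from 3.87 ± 1.34 TPM (SD, n = 3) for Plagl1 to 724 ± 48.5 TPM for Tnfrsf4, which encodes the costimulatory receptor OX40. Foxp3, the lineage-defining transcription factor (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245, plus strand), stood at 134.5 TPM in library 1, 149.6 TPM in library 2 and 106.3 TPM in library 3, with 6200.4 to 6800.2 expected counts per library. Il2ra, the interleukin-2 receptor alpha chain CD25 (chromosome 2, 11642807 to 11693193), had 158 ± 6.12 TPM, and Il2rb, its signalling partner, had 717 ± 94.0 TPM. Ctla4, an inhibitory receptor (chromosome 1, 60887000 to 60915832), had 287 ± 56.6 TPM. Ikzf2, which encodes Helios (chromosome 1, 69531214 to 69687245), had 218 ± 20.1 TPM over all its transcripts. Transcript estimates placed 69.8% of this on Ikzf2-205, annotated as a retained intron, and 16.0% on the coding Ikzf2-201. Tnfrsf18, which encodes GITR, had 444 ± 67.8 TPM, and Izumo1r, the folate receptor FR4, had 365 ± 52.1 TPM. The list's median of 107.3 TPM lay above the medians of all 10000 random protein-coding lists of the same size. The resting, T cell receptor, glycolysis and erythroid lists also lay above all their random lists, so this rank is not particular to Treg genes.

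**Figure D1:**
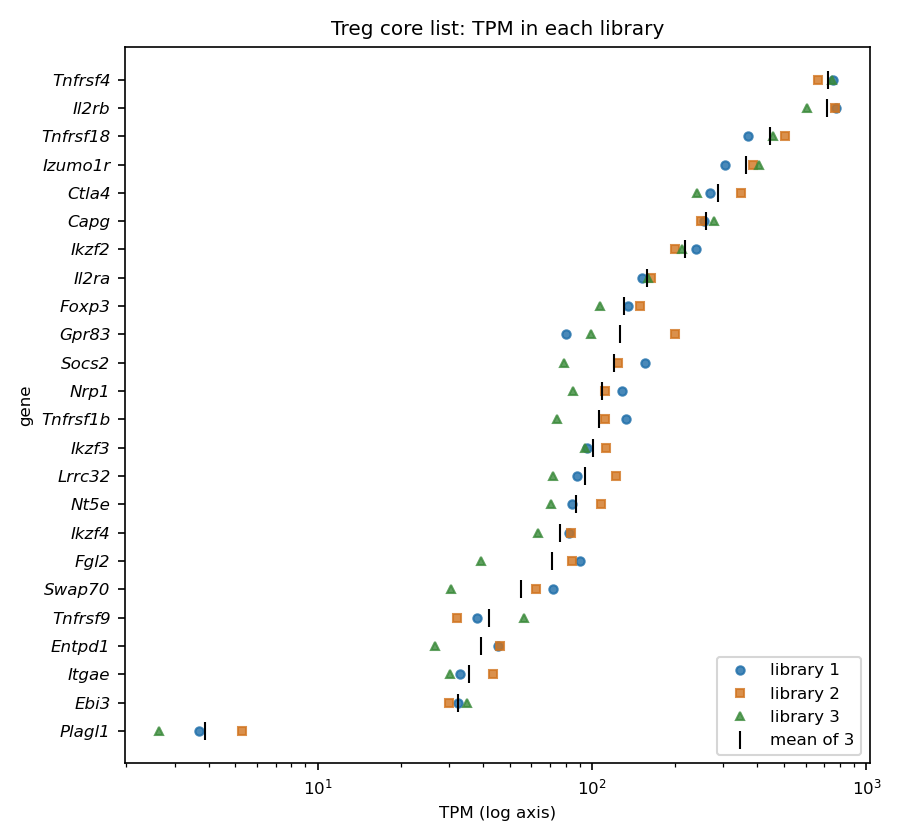
TPM on a log axis (x) of the 24 Treg core genes (y) in each of the 3 libraries; coloured symbols are libraries and the black bar is their mean. All genes but Plagl1 have means from 32.5 TPM for Ebi3 up to 724 TPM for Tnfrsf4.

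Genes of the Treg core list were more abundant here than genes listed for the other CD4 helper lineages. Their mean log2(TPM + 1) was 6.81 over 24 genes against 3.24 over the 28 genes of the Th1, Th2, Th17 and Tfh lists, a difference of 3.57 (two-sided permutation test across genes, adjusted p = 6.0e-05, from the smallest p that 100000 resamples can give). The difference was above 0 in each library, from 3.38 in library 1 to 3.84 in library 2. Over detected members only, 24 Treg core and 17 helper genes, it was 1.95. Th17 genes were close to absent: 1 of the 7 members was detected, and Il17a had 0.127 ± 0.1002 TPM. The other lineages were not at background. Gata3, a Th2 regulator that Treg also express, had 145 ± 54.6 TPM, Il4 93.4 ± 21.6 TPM, Stat4 119.6 ± 16.8 TPM and Tbx21, the Th1 regulator, 25.5 ± 17.5 TPM. Slamf6 at 465 ± 95.8 TPM and Sh2d1a at 130.4 ± 13.2 TPM, listed with Tfh genes but used by many T cells, exceeded the Tfh regulator Bcl6 at 9.42 ± 2.15 TPM. Genes are not independent replicates, and the series holds no sample of another CD4 lineage. This p-value therefore describes the lists within 1 biological sample and depends on which genes they hold.

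Genes of activated or effector Treg and genes of resting or central Treg were present together, and the resting genes were the more abundant. All 32 activated-list members and all 21 resting-list members were detected. The median was 62.3 TPM for the activated list and 286 TPM for the resting list. The mean log2(TPM + 1) was 6.09 and 7.41, a difference of -1.31 (two-sided permutation test across genes, adjusted p = 0.0140). The sign was the same in each library, with -0.78 in library 1, -1.32 in library 2 and -1.90 in library 3. Among activated-list genes, the transcriptional regulator Id2 had 628 ± 272 TPM, the integrin Itgb1 615 ± 240 TPM, the costimulator Icos 326 ± 42.9 TPM, Batf 255 ± 32.05 TPM, Il10 33.7 ± 11.1 TPM and Prdm1, which encodes Blimp-1, 22.4 ± 8.65 TPM. Among resting-list genes, Tcf7 had 728 ± 58.9 TPM, the lymph-node homing receptor Ccr7 572 ± 113 TPM and Klf2 512 ± 74.8 TPM. Without library 3 the difference was -1.04 and the adjusted p of the permutation test was 0.0592, so the call rests on that library. As a difference of medians it was -2.18. The series holds no resting Treg sample here, so the comparison is between gene lists and not between cell states.

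Of the 16 gene pairs chosen in advance, 12 had a ratio larger than the spread between libraries. Ratios are log2((TPM + 1) / (TPM + 1)), which understate ratios with low genes. Cd4 exceeded Cd8a by 6.61 ± 0.89 (SD, n = 3), Trac exceeded Trdc by 9.14 ± 0.21, and Foxp3 exceeded Bcl6 by 3.66 ± 0.45 and Tbx21 by 2.502 ± 0.83. Il10 exceeded Il2 by 3.34 ± 0.55. Foxp3 and Gata3 did not differ beyond the spread, at -0.08 ± 0.41. On the side of resting genes, the Ccr8 to Ccr7 ratio was -2.66 ± 0.79 and the Batf to Tcf7 ratio -1.51 ± 0.13. The other way, the activated-list gene Id2 exceeded the resting-list gene Id3 by 2.53 ± 0.96. The ratios of Icos to Ccr7, Prdm1 to Bach2 and Il2ra to Il7r, at -0.80 ± 0.42, -0.95 ± 0.76 and -1.04 ± 0.57, were below 0 in each library but under 2 SD. In the other deposited gene table, whose counts are not divided by length, Ccr8 to Ccr7 was -0.86, Id2 to Id3 0.95, Foxp3 to Bcl6 2.497, Foxp3 to Tbx21 1.75 and Cd4 to Cd8a 5.90. The Ikzf2 to Ikzf4 ratio of 1.51 ± 0.24 was reversed there at -0.75. Of the Ikzf2 TPM, 69.8% fell on a transcript annotated as a retained intron.

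**Figure D2:**
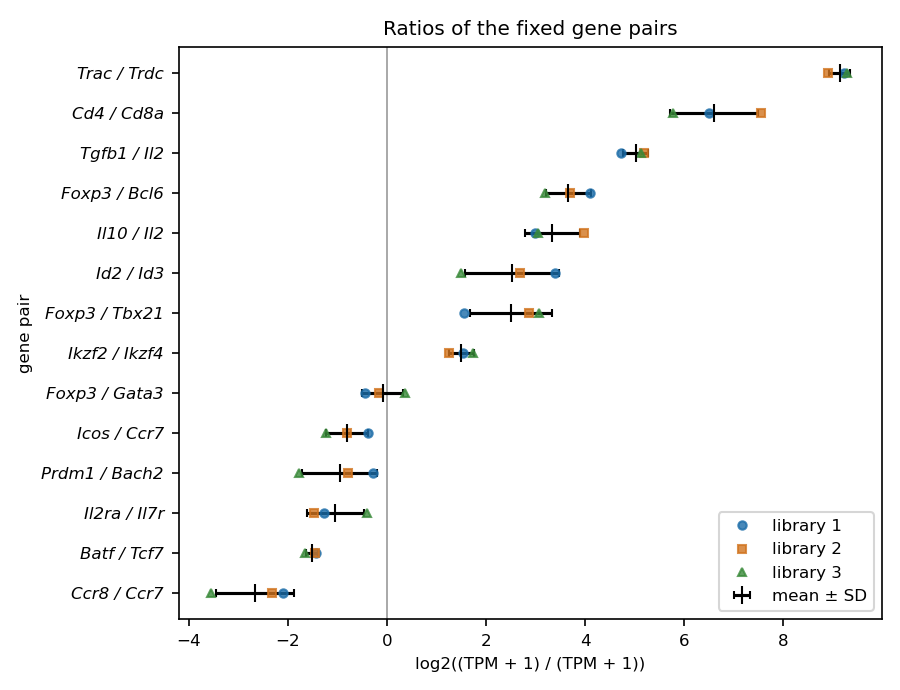
Log2 ratio of TPM + 1 (x) for 14 of the gene pairs (y); coloured symbols are libraries, and the black bar with whiskers is the mean ± SD of the 3. Trac / Trdc has the highest mean at 9.14 and Ccr8 / Ccr7 the lowest at -2.66, and Foxp3 / Gata3 has libraries on both sides of 0.

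T cell receptor, costimulatory, glycolysis and fatty acid oxidation genes had list medians above the middle 95% of random lists, also against detected protein-coding genes. Cytokine and cholesterol synthesis genes did not, and homing receptor and immediate early genes did only against all protein-coding genes. Undetected members stayed in the lists when only detected genes were drawn at random, which lowers lists with many such members. The T cell receptor list had a median of 740.2 TPM, with Trbc2 at 3063 ± 505 TPM. Costimulatory and inhibitory receptors had a median of 76.1 TPM with 19 of 20 detected. Among homing receptors, 21 of 25 were detected, with the gut-associated integrin Itgb7 highest at 718 ± 63.1 TPM. Of 25 cytokine and growth factor genes, 15 were detected. Ltb, which encodes lymphotoxin beta, was highest at 986 ± 190.3 TPM, followed by Penk, the proenkephalin gene, at 209 ± 36.7 TPM and Tgfb1 at 106.6 ± 2.73 TPM. Il2 had 2.34 ± 0.527 TPM, and Il9 had no read in any library, which allows up to 3 reads in each. Glycolysis genes, led by Ldha at 1167 ± 50.3 TPM, had a median of 134.7 TPM. Fatty acid oxidation genes had a median of 68.1 TPM with all 14 detected, and cholesterol synthesis genes a median of 15.5 TPM with 14 of 16 detected. In the immediate early and stress list 16 of 21 were detected, with Nfkbia at 628 ± 67.3 TPM and Hspa1a at 0.237 ± 0.230 TPM. In all, 13 of the 32 lists had a median above the middle 95% of random protein-coding lists, and 9 of 32 did so against detected protein-coding genes. Both counts include the erythroid list, whose place rests on library 1. Against all protein-coding genes its percentile was 90.89 without that library and 77.49 in the other deposited gene table.

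Proliferation genes and quiescence genes were both expressed and did not differ past the threshold. The 25 proliferation genes had a mean log2(TPM + 1) of 5.01 and the 14 quiescence genes 6.23, a difference of -1.22 (two-sided permutation test across genes, adjusted p = 0.0710). All 25 proliferation genes were detected, led by Pcna at 159 ± 19.7 TPM, and Mki67 had 16.4 ± 9.47 TPM. Txnip led the quiescence list at 929 ± 284 TPM, and the lowest member was Klf4 at 0.367 ± 0.241 TPM. The difference passed the threshold as medians (-1.07), without library 1 (-1.58) and over detected members only (-1.66). That last setting left out 1 quiescence gene, Klf4, and no proliferation gene, so it could only widen the difference. In the other deposited gene table the difference was -0.21 (permutation test, adjusted p = 0.747).

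Markers of other cell types ranged from not detected to a mean of 1884 TPM for the globin Hbb-bs, a mean carried by library 1. None of 8 neutrophil genes was detected at 1 TPM or more in all 3 libraries. Their median was 1.42 TPM in library 1, against 0.08 TPM in library 2 and 0.115 TPM in library 3. Of 6 platelet genes and of 5 mast cell and basophil genes, 1 each was detected. Detected members numbered 2 of 7 for natural killer cells, with Gzma at 22.7 ± 7.80 TPM, 3 of 8 for dendritic cells, with Cd74 at 299 ± 161 TPM, 2 of 10 for stromal, endothelial and epithelial cells, 1 of 5 for thymocytes, which was Cd1d1 at 88.5 ± 8.69 TPM, 4 of 5 for gamma-delta T cells and 6 of 8 for monocytes and macrophages, led by Lyz2 at 47.4 ± 21.4 TPM. Cd8a had 2.86 ± 1.33 TPM and Cd8b1 22.1 ± 2.83 TPM. In the B cell list 8 of 10 were detected, led by Ighm at 295 ± 45.4 TPM, but the list median was 4.61 TPM and Pax5 had 0.147 TPM. In the plasma cell list 4 of 6 were detected, led by Igkc at 576 ± 64.7 TPM, but the list median was 11.9 TPM and Sdc1 had 0.473 TPM. In the erythroid list 7 of 8 were detected. The Y-linked genes Eif2s3y at 117 ± 22.5 TPM, Ddx3y at 67.9 ± 4.42 TPM, Uty and Kdm5d were expressed, and Xist had 0.0633 ± 0.0473 TPM; the labels give a male.

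The libraries differed from each other well beyond counting noise. Of 17190 genes with a mean of 10 or more reads, 13747 (79.97%) differed at a Benjamini-Hochberg threshold of 0.05 in a chi-square test of the 3 counts against library size, and 8880 of 16415 did so between libraries 1 and 2 alone, without library 3. Of 11992 genes tested in the other deposited gene table, 7828 differed. The test compares these libraries, not conditions. No pair agreed within sampling noise, so none was treated as one library deposited again. Most differences were small: over 11109 genes with 100 or more reads on average, the highest library exceeded the lowest by a median of 1.33-fold, and 1040 exceeded 2-fold. The common coefficient of variation beyond counting error was 0.375 by edgeR. All 24 Treg core genes, all 25 proliferation genes and all 21 resting-list genes passed the chi-square test, with the same numbers when adjusted over the list alone. Most well-counted genes passed too, 10968 of 12531 with a mean of 50 or more reads, so passing does not set these lists apart.

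Red-cell genes separated the libraries most. The 4 adult globin genes had the 4 largest chi-square values. Hbb-bs, a beta-globin (chromosome 7, 103826534 to 103828096, minus strand), had 4958 TPM in library 1, 393.5 TPM in library 2 and 301.9 TPM in library 3, and Hba-a2, an alpha-globin, 4459, 411.7 and 256.6 TPM. Globin genes are near-identical copies, so their split between copies is uncertain. Slc4a1, the red-cell anion exchanger (chromosome 11, 102348824 to 102366203), had 119.5, 5.56 and 2.48 TPM, and Alas2, the erythroid heme synthesis enzyme, 69.9, 5.68 and 4.14 TPM. All 8 erythroid genes were highest in library 1, by a median of 13.7-fold against the mean of the other libraries. In the other deposited gene table, which is compressed at high counts, that median was 3.64-fold, with 7 of 8 highest in library 1. The 4 globin genes together took 0.453% of the gene reads of library 1 and 0.0292% of those of library 3. Tmsb4x, Serinc3 and Actb completed the 8 genes with the largest chi-square values. Serinc3 had 846.5, 1215 and 487.1 TPM, and Actb 2117, 1636 and 3010 TPM.

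Gene lists moved together between libraries. Each list's median difference between a library and the mean of the other 2 was set among 10000 random lists matched on expression, a description chosen after seeing the data. Of 75 such positions over 25 lists, 30 lay outside the middle 95%, where 3.75 would by chance. The 3 positions of a list depend on each other and some lists share genes, so the 75 are not independent. Library 1 had the highest value for 22 of 25 proliferation genes and a list median 1.92-fold above the others. Rrm2, a subunit of ribonucleotide reductase, had 95.8, 26.2 and 46.8 TPM in libraries 1, 2 and 3, and Mki67 27.3, 11.2 and 10.7 TPM. Library 1 also held more of the activated or effector genes, with 22 of 32 highest there and a median 1.31-fold above, more Th1 genes, with a median 2.11-fold above and Ifng at 26.5, 5.76 and 6.64 TPM, and more cholesterol synthesis genes, with 13 of 16 highest. It held less of the resting genes, with 18 of 21 lowest there. The erythroid, dendritic and monocyte lists were higher in library 1 too, beside these groups. In the other deposited gene table the log2 median of the activated list was smaller, at 0.11 in library 1 and -0.18 in library 3, as was that of the resting list, at -0.18 and 0.11, and that of the interferon-response list in library 3, at 0.29.

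Library 3 had higher resting and interferon-response genes and lower effector genes. Beside them it had the largest shares of ribosomal protein reads, 3.67% against 2.53% and 2.84% in libraries 1 and 2, and of pseudogene reads, 2.17% against 1.65% and 1.64%. Across 17179 genes, which are not independent replicates, its differences from the other libraries had a Spearman rho of -0.443 with transcript length, against 0.252 for library 1 and 0.333 for library 2. Of the resting list 16 of 21 were highest in library 3, and Ccr7 had 488, 528.5 and 700.6 TPM in libraries 1, 2 and 3. Of the activated list 23 of 32 were lowest there. Interferon-response genes were 1.44-fold above the other libraries by the list median, with Ifit1 at 15.8, 13.4 and 38.4 TPM and Isg15 at 27.3, 19.7 and 58.4 TPM. B cell genes were also higher in library 3, 1.88-fold by the median, with Ms4a1, which encodes CD20, at 2.19, 1.67 and 5.98 TPM. Library 2 held the lowest value for 24 of 25 proliferation genes, 19 of 20 interferon-response genes and 9 of 10 B cell genes, and its dendritic list was 2.64-fold below the others, with Cd74 at 459.9, 137.7 and 300.9 TPM.

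**Figure D3:**
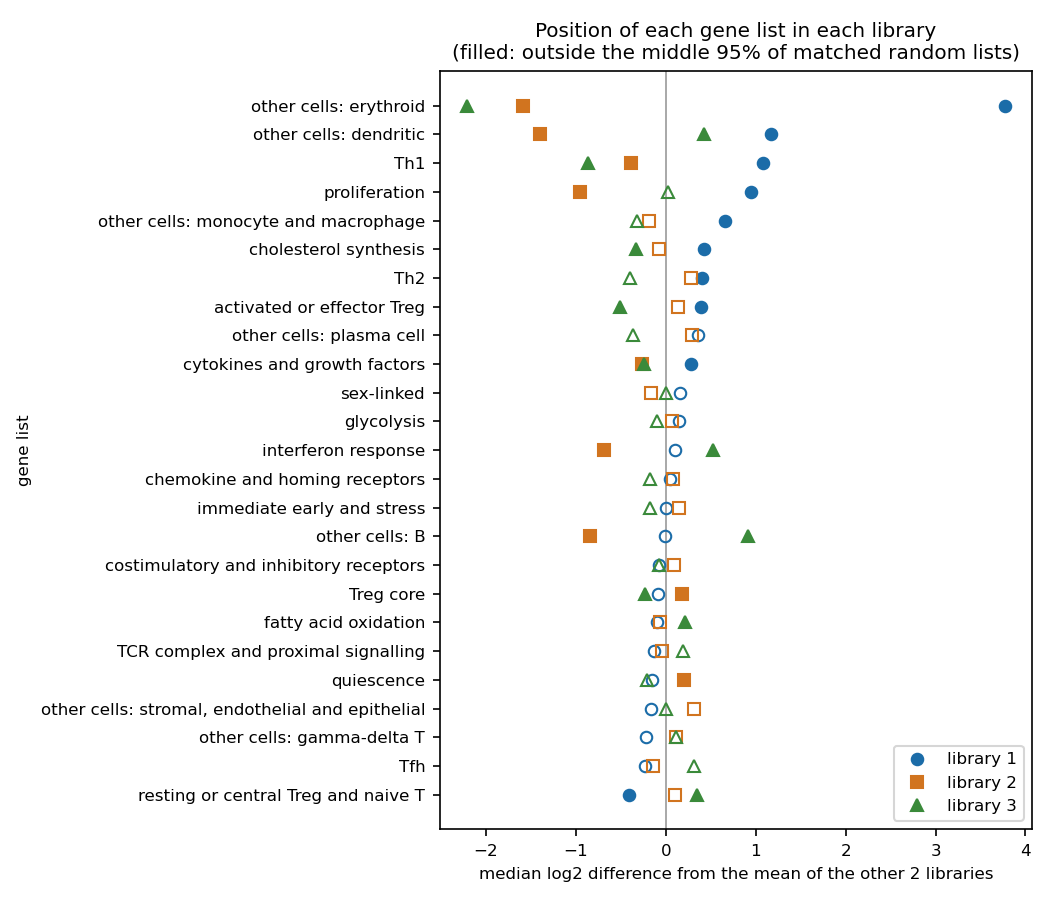
Median log2 difference of each gene list in a library from the mean of the other 2 (x), for the 25 lists with 5 or more tested members (y); symbols are libraries, filled outside the middle 95% of 10000 matched random lists and open inside it. The erythroid list of library 1 is the farthest point at 3.77, and proliferation lies at 0.94 in library 1 and -0.95 in library 2.

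Transcript estimates placed most of the 16 genes examined on 1 main transcript, since 12 had one transcript at 50% or more in each library. Ctla4-201, the full-length receptor transcript, took 99.6 ± 0.311% (SD, n = 3), and Pkm-201 took 95.4 ± 0.464%. Foxp3 was divided between a coding transcript of 12 exons (7579567 to 7593799) at 49.6 ± 2.49%, a coding transcript of 13 exons (7579669 to 7595234) at 29.6 ± 0.708% and a nonsense-mediated decay transcript at 15.1 ± 2.09%. For Ikzf2 the largest share, 69.8 ± 1.67%, fell on Ikzf2-205, annotated as a retained intron, and 16.0 ± 1.74% on the coding Ikzf2-201. Tcf7-201 took 76.0 ± 1.21%, Il2ra-201 73.4 ± 4.11%, Cd44-203 60.02 ± 2.24% and Il7r-201 71.4 ± 2.70%. These shares are model estimates from short reads.

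T cell receptor V segment use was broad. Among beta segments, 19 of 35 took 1% or more of the Trbv reads, with Trbv3 at 13.0 ± 0.989%, Trbv19 at 12.0 ± 0.907%, Trbv16 at 8.77 ± 0.378%, Trbv13-2 at 7.56 ± 0.868% and Trbv1 at 6.96 ± 0.948%. The effective number of Trbv segments was 16.8 ± 0.0894. Among alpha segments, 34 of 128 took 1% or more, led by Trav7-4 at 4.01 ± 0.509% and Trav9-1 at 3.54 ± 0.477%, and the effective number was 74.9 ± 2.33. Many Trav segments are close copies, so their split is uncertain.

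The most abundant gene was Tmsb4x, which encodes thymosin beta 4, at 12048 ± 2193 TPM, followed by the class I gene H2-K1 at 10966 ± 1143 TPM. The 10 most abundant genes took 4.32 ± 0.342% of the gene reads and the 100 most abundant 16.1 ± 1.15%, or 24.5% by TPM. Mitochondrial genes took 1.39 ± 0.173% and ribosomal protein genes 3.01 ± 0.588%. Each library had 2 deposited gene tables, and across 22195 shared genes their log2 values correlated with a Spearman rho between 0.936 and 0.949 and a Pearson r between 0.947 and 0.961 per library. These correlations are across genes, which are not replicates. Of 381 list genes, 142 to 158 differed by over 2-fold between the tables at the same total, with 65 to 67 lower and 77 to 91 higher in the smaller table.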

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

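All tests of explanations in this part were chosen after the result was seen.

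Outside the gene measurements, phiX sequence, a common sequencing control, took 59884 reads in library 1, 45009 in library 2 and 69706 in library 3, above the 3 reads that a count of 0 allows. These are 0.197%, 0.158% and 0.218% of all reads, with 95% Wilson intervals of 0.195 to 0.198%, 0.157 to 0.160% and 0.216 to 0.219%. The ERCC spike-ins had 0 reads in each library. Transfer RNA entries took 2534, 2295 and 3594 reads, also above that limit.

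Red-cell transcripts were about 13.7-fold higher in library 1, and 3.64-fold in the smaller gene table, which is compressed at high counts. Reads shared between globin copies do not account for it, since the 4 erythroid list members that are not globins were higher by a median of 14.3-fold, from 12.1-fold to 29.4-fold. Removing a trend in GC content and length left the list's median difference at 3.88 on the log2 scale. RNA of red cells or their precursors in library 1 is a candidate source: 15 red-cell genes outside the list, such as Klf1, Rhd and Hemgn, were higher there by a median of 10.04-fold, from 1.51-fold to 18.7-fold, beside Hbb-bs at 4958 TPM. The labels name no sort or gate that would remove such cells, and how many of these genes Treg express was not determined. No other biological explanation was tested.

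Gene lists set the libraries apart at 30 of 75 positions. After removing the GC and length trend, which held 19.0% of the variance of library 3 over well-counted genes, 27 of the 30 stayed outside the middle 95% and 8 others joined them, 35 in all, so it does not account for the whole pattern. In the smaller gene table, whose values are compressed at high counts, 22 of the 30 stayed outside. Its treatment of repeated reads is not given in the sources used here. That table therefore leaves repeated counting of amplified reads open for the lists as a whole. Immunoglobulin V genes, each of which few cells use, differed between libraries more than random genes of like abundance, at percentile 100.0 with a median dispersion index of 50.6 against 5.46, but they were examined because some had been seen to vary, so this does not bear on whether the libraries are separate samplings of cells. Trbv segments lay at percentile 99.2 and Trav segments at 0.53. The Trbv total itself differed, at 12635, 11516 and 19263 reads in libraries 1, 2 and 3. With counts scaled within the family, the median Trbv index was 6.79 in place of 35.1. Whether the libraries are separate samplings of cells stays open.

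The proliferation list was higher in library 1. Its percentile stayed at 100.0 with the GC and length trend removed, with a median of 0.95 on the log2 scale, and at 100.0 in the smaller gene table, with 0.76. The trend does not account for it. With or without the trend, all 25 members were above the other libraries in library 1, and 0 were in library 2. Repeated counting that acts gene by gene would affect the matched random lists alike, so these values argue against it for this list. The smaller table cannot decide this, since its treatment of repeated reads is not given in the sources used here. The share of dividing cells per library was not tested, nor which cells the transcripts came from, and no biological explanation was tested.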

How the results depend on the processing

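The settings below were planned except the list positions, the other gene table for the coefficient of variation, and the left-out libraries for the table comparison. Genes detected ranged from 9702 to 16452, lists above random ones from 9 to 15, gene pairs beyond the spread from 11 to 13, genes with a main transcript from 12 to 13 and list positions from 22 (of 66) to 35. The 9 lists were placed with all members against detected genes, and the 15 with detected members only against all protein-coding genes. The Treg core against helper difference stayed past the threshold at 1.95 to 4.21. Of single list positions, 8 lost and 8 gained their place outside the middle 95% under a GC and length correction or the smaller table; those named in the report were not among the 8 lost. Genes that differ between libraries fell from 13747 to 7828 in the smaller gene table, where 11992 were tested, and ranged from 8880 (without library 3) to 11773 with 1 library left out; each of these holds fewer counts or libraries. The coefficient of variation of 0.375 was 0.516 with genes of 1 or more reads, 0.272 with 50 or more, 0.260 in the smaller table and 0.296 to 0.427 with 1 library left out. The activated minus resting difference ranged from -1.59 to -1.04 with 1 library left out, with adjusted p = 0.0592 by permutation without library 3 and from 0.00237 under the other settings. The proliferation minus quiescence difference passed the threshold as medians (-1.07), without library 1 and with detected members only (-1.66), which leaves out Klf4 alone. It ranged from -1.58 to -0.91 over left-out libraries, and the adjusted p ranged from 0.00954 to 0.747 by permutation over the settings. The cause was not tested. The effective number of Trbv segments was 17.7 by TPM and 16.5 over functional segments, and the share of the top 100 genes was 24.5% by TPM. The log2 ratio of Ikzf2 to Ikzf4 reversed to -0.75 in the smaller table, and Ccr8 to Ccr7 moved to -0.86 and Foxp3 to Bcl6 to 2.497; its counts are not divided by length. No paired analysis was possible because there is 1 group. Depth limits genes under about 10 reads, which the main chi-square test left out. With a mean of 1 or more reads, 18755 of 30520 tested genes differed.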

Other observations

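The test of glucocorticoid genes below was written before its result was seen; the genes that prompted it, and the immunoglobulin genes, were chosen after their values were seen.

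Immunoglobulin genes had a library-specific make-up. Ighg2b had 30.9 TPM in library 1, 2.91 TPM in library 2 and 0.23 TPM in library 3, and Igha had 20.7, 0.17 and 0.13 TPM. Ighg1 was instead highest in library 2, at 99.5, 271 and 134.2 TPM. Igkv1-110 had 1.41, 38.3 and 38.7 TPM, while the constant gene Igkc differed little, at 579.3, 638.9 and 509.6 TPM. T cell receptor alpha segments had a median dispersion index of 4.36 over 104 Trav segments against 6.72 in random genes of like abundance, at percentile 0.53. Over 22 Trbv segments the index was 35.1 against 15.8, at percentile 99.2. All Trbv segments together took 12635, 11516 and 19263 reads in libraries 1, 2 and 3, and with counts scaled within each family the median index was 6.79 for Trbv and 2.13 for Trav.

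Several genes known to be induced by glucocorticoids were highest in library 2. Fkbp5 had 187, 359.9 and 82.8 TPM in libraries 1, 2 and 3, Tsc22d3 358, 658 and 405 TPM, and Klf9 4.67, 7.25 and 1.31 TPM. The hypothesis that glucocorticoid response differs between libraries was tested on 16 other inducible genes. In library 2 their median lay 0.19 above the other libraries on the log2 scale, at percentile 95.95 among matched random lists, which is between the bounds set in advance for and against, so the test left it open. In library 3 their median lay at -0.49 and percentile 0.11. Ddit4 had 78.9, 165 and 99.8 TPM, but Mt1 was highest in library 1, at 56.1, 25.6 and 13.6 TPM.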
